A study of Mus musculus with 18 samples.

How the data were processed

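RNA of mouse lung cancer cell lines was sequenced in 18 libraries, 3 in each of 6 groups. Per the labels' protocols, libraries were made with a stranded Illumina mRNA kit and read for 75 bases on a NextSeq instrument; the protocol names both single-end and paired-end runs, and which applies to a given library was not given in the sources used here. Per the submitters' processing notes, kallisto and sleuth were used with the mouse build mm10, without versions. The deposited values are estimated counts per transcript, made by the authors with kallisto, which assigns reads to transcripts by pseudoalignment and shares a read among transcripts it fits equally well. These estimated counts are not whole numbers and were not normalized. The deposited effective transcript lengths came with them. The authors' normalized transcript values were not used. Shared reads make the counts of near-identical genes uncertain, which concerns the Ly6, Xlr3, Trim30 and H2 families, ribosomal proteins with processed pseudogenes, and mitochondrial genes with nuclear copies.

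Each library listed 118489 transcripts. Of these, 116816 matched a gene of GENCODE mouse release M21, which is on GRCm38, the assembly also called mm10, and 36047 genes had a listed transcript. The 1673 transcripts without a match held between 0.515% and 0.593% of the counts of a library and stayed out of library sizes and tests. Estimated counts were summed per gene and rounded to whole numbers. Libraries held between 40525385 and 46528071 estimated counts, and the 10 most abundant genes took between 4.61% and 6.23% of them. Reads were not marked by molecule, so repeated reads of one molecule are not told apart in these counts.

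Groups were taken from the sample titles, because the phenotype label is the same for the empty vector and the altered arm of an experiment. The labels give replicate numbers but do not say that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. In the 18 pairs of libraries within a group, the mean chi-square per gene was 1.93 or more, so no library was a copy of another. Values of 13.35 and 15.19 for the first library of UN-SCC679 with empty pLENTI6 against the other libraries of its group stood above 5.28, the highest value of any other pair.

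Each comparison of an altered arm with its own empty-vector arm used the 6 libraries of that experiment in R 4.3.3 with edgeR 4.0.16. Scaling was by trimmed means of M-values (TMM), genes were kept by edgeR's default filter (a minimum count of 10 and a total of 15), and the quasi-likelihood test was used with Benjamini-Hochberg adjustment. A gene is called changed at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the test's F statistic, and CPM values, which are counts relative to library size after TMM scaling, are given as mean ± SD. Differences between effects were tested as interactions on 12 libraries in 4 groups. Overlaps of calls were set beside the number expected of independent lists of the same sizes among the genes tested in both fits; no library was shared between the comparisons overlapped.

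Before the data were examined, 25 gene lists were fixed: lysosome, autophagy, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, the ATF4 amino acid response, the unfolded protein response, the NRF2 antioxidant response, TNF and NF-kB targets, interferon response, MHC class I antigen presentation, ligands and receptors of T and NK cell killing, epithelial, mesenchymal, squamous, alveolar and club cell markers, S phase, G2 and M phase, p53 targets, ERK pathway targets, cholesterol synthesis, glycolysis and hypoxia, cytosolic ribosomal proteins, and leukocyte, fibroblast and endothelial markers. Lists were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 75 tests. Beside it stands camera with a correlation estimated per list, which also bases its p on the residual degrees of freedom (4 in each comparison). Camera.DGEList, which works on the counts, is given as an alternative. Camera compares a list with all other tested genes, so a list can be called when its members lie only slightly to one side. Counts of changed members are given adjusted over all tested genes and adjusted over the list alone; where one count is given, both were equal.

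The rule for named genes was also fixed then. It takes Dstyk; in each comparison the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean log2 CPM of at least 3, a curated symbol and no overlap between the libraries of the groups; the 2 called members of each list with the smallest adjusted p; and the 5 genes each way with the largest changes in the same direction in both knockdowns, and in opposite directions in knockdown and overexpression. Not all of them are named, and 1 result is not reported here.

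The procedure was tested on simulated counts drawn from the means and library sizes of each comparison, with 200 genes changed in each of 3 simulations. At a mean log2 CPM of at least 3, all seeded changes of 1.5-fold or more were recovered in the LLC knockdown (13531 genes), the UN-SCC679 knockdown (14040 genes) and the UN-SCC679 overexpression (13813 genes), and 1.25-fold changes were recovered for 87.2%, 84.4% and 91.2%. Over all seeded genes in LLC, 73.6% of 1.5-fold and 78.1% of 2-fold changes were recovered. The share of false calls was 9.3%, 9.9% and 10.8%, above the nominal 5%, so calls near the threshold are less certain than their adjusted p. Far fewer genes were changed than are called in the real data, so these shares need not carry over. With the lysosome list alone shifted by 0.3 (log2), camera called it in each comparison and 1 other list in LLC. Simulated genes were drawn independently of each other, so this cannot show how often camera calls lists of correlated genes falsely. Regrouped real libraries gave up to 8 called lists in LLC, 9 in the UN-SCC679 knockdown and 6 in the overexpression. In simulations of the interactions the share of false gene calls was 6.8% between the lines (14977 genes) and 4.7% between knockdown and overexpression (14628 genes).

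Alternatives fixed in advance were edgeR's RLE size factors, library size alone, the DESeq2 1.42.0 Wald test, limma on log2(TPM + 1) with TPM recomputed from estimated counts and effective lengths, no filter on low counts, a filter of 1 CPM in 3 libraries, an offset for effective length, protein-coding genes alone, all 18 libraries in one fit, a block for replicate number, a size limit of 2-fold, and leaving out each library in turn. A per-chromosome offset and camera.DGEList as a separate setting were added after the data were seen. Other calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.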

Results

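The data are transcript counts from 2 mouse lung cancer cell lines in which the dual serine/threonine and tyrosine kinase DSTYK was lowered or raised. LLC (Lewis lung carcinoma) is labelled lung adenocarcinoma and comes from C57BL/6 mice, and UN-SCC679 is labelled lung squamous carcinoma and comes from A/J mice. In each line, 3 libraries of cells with the sh3 construct in the TPLKO vector were compared with 3 libraries of the empty TPLKO vector, all with doxycycline. In UN-SCC679, 3 libraries of cells with wild-type DSTYK in the pLENTI6 vector (OE_DSTYKwt) were compared with 3 libraries of empty pLENTI6. Libraries held between 40525385 and 46528071 estimated counts. The coefficient of variation between libraries of a group, from edgeR's common dispersion, was 2.65% in the LLC knockdown, 3.76% in the UN-SCC679 knockdown and 3.79% in the overexpression. It may be technical, because the labels do not say that replicates were separate cultures. The median size of a called log2 change was 0.42, 0.34 and 0.22 in that order. The question of the comparisons was how the transcriptome of these lines responds when DSTYK is altered.

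In LLC, Dstyk fell from 42.75 ± 2.07 CPM with the empty vector to 23.07 ± 0.790 CPM with sh3 (SD, n = 3), a 1.85-fold reduction (log2 -0.89, SE 0.044; adjusted p = 9.81e-10, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The gene (ENSMUSG00000042046.15) lies on the plus strand of chromosome 1 at 132417555 to 132466958 of GRCm38, and every sh3 library lay below every empty library. Changes were widespread: 9995 of 13767 tested genes (72.6%) passed the test, 4984 higher and 5011 lower, of which 1111 rose and 572 fell at least 2-fold (1683 in all, against 666 with limma on log2(TPM + 1)). The median log2 change of the genes of chromosome 1 was 0.14. The groups did not overlap for 76% of genes, where chance gives 10%.

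Among genes with a mean log2 CPM of at least 3, the strongest rises in LLC included Ndrg2, from 3.04 ± 0.177 to 35.0 ± 1.22 CPM (11.5-fold). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose from 291 ± 5.29 to 1551 ± 13 CPM (5.32-fold). Sort1, a sorting receptor that carries proteins from the Golgi to endosomes and lysosomes, rose 6.37-fold, the serine/threonine kinase gene Pim1 rose 5.63-fold, and Ccn1, a secreted matricellular protein, rose 5.42-fold. The strongest fall was that of Angptl4, a secreted inhibitor of lipoprotein lipase, from 38.4 ± 0.862 to 1.70 ± 0.205 CPM (22.6-fold). Cpt1a, whose product brings long-chain fatty acids into mitochondria, fell from 162 ± 5.62 to 33.8 ± 0.811 CPM (4.80-fold), Angpt1, a ligand of the receptor Tie2, fell 4.59-fold and the Wnt inhibitor gene Apcdd1 fell 4.01-fold. All of these had n = 3 per group and an adjusted p of at most 1.23e-10 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

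Antigen presentation genes were higher in LLC with sh3: of 16 members of the MHC class I list, 12 rose and 3 fell (4 fell when adjusted over the list alone), with a median log2 change of 0.85. H2-K1, a class I heavy chain, rose from 9.44 ± 0.582 to 37.8 ± 0.967 CPM and B2m, the class I light chain, from 245 ± 3.45 to 541 ± 7.28 CPM. Of 19 ligands and receptors of T and NK cell killing, 11 rose and 3 fell (median 0.38). Pvr and Nectin2, ligands of receptors on T and NK cells, rose 2.34-fold and 2.41-fold. The list mixes genes that promote and genes that inhibit killing, so its counts give no direction of killing. Of 35 lysosome genes, 23 rose and 4 fell (median 0.40), among them Psap, the precursor of the saposins, up 1.42-fold, and the protease gene Ctsb, up 1.41-fold. The NRF2 list had 17 of 21 members higher and 4 lower (median 0.57); Nqo1, a quinone reductase, rose 3.49-fold and the glutathione-conjugate exporter gene Abcc1 rose 2.20-fold. Camera with Benjamini-Hochberg adjustment called these lists at adjusted p = 0.0191 (MHC class I), 0.0234 (killing), 2.05e-04 (lysosome) and 5.36e-05 (NRF2). With an estimated correlation the adjusted p was 0.214, 0.336, 0.170 and 0.119 in that order.

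S phase genes fell in LLC, 36 of 42 against 4 that rose (5 when adjusted over the list alone), with a median of -0.42; the replication helicase genes Mcm5 and Mcm7 fell 2.01-fold and 1.80-fold. Nuclear genes of oxidative phosphorylation fell in 47 of 72 cases and rose in 9 (48 and 9 when adjusted over the list alone; median -0.18), among them the ATP synthase gene Atp5a1, down 1.43-fold, and Ndufa4, down 1.37-fold. Ribosomal protein genes rose in 64 of 74 cases and fell in 3 (median 0.24). Cholesterol synthesis genes rose in 18 of 23 cases and fell in 2 (19 and 2 when adjusted over the list alone; median 0.43), among them Fdft1, which makes squalene, up 1.79-fold, and the regulator gene Srebf2, up 1.47-fold. Of 19 genes of the unfolded protein response 13 rose and 4 fell (median 0.17), with the endoplasmic reticulum chaperone gene Hyou1 up 1.52-fold and the disulfide isomerase gene Pdia6 up 1.61-fold. ERK pathway targets rose in 13 of 20 cases and fell in 2 (median 0.18), with Dusp4, a phosphatase acting on ERK, up 2.68-fold. Camera's adjusted p (Benjamini-Hochberg) was 1.48e-08 for S phase, 2.05e-04 for oxidative phosphorylation, 1.25e-11 for ribosomal proteins, 2.91e-05 for cholesterol synthesis, 0.0108 for the unfolded protein response and 0.00684 for ERK targets. With an estimated correlation these were adjusted p = 0.0798, 0.282, 0.282, 0.119, 0.246 and 0.214.

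In all, 10 lists were called in LLC, and other splits of the same 6 libraries called up to 8. The other lists were not called in LLC, with camera's adjusted p from 0.0766 to 0.994. The mitochondrially encoded list was called lower with camera.DGEList (adjusted p = 0.0196) and without the third library of either arm (0.0324 and 0.0436), over alternatives from 0.0196 to 0.688. Within them, higher and lower members numbered 14 and 8 of 31 for autophagy, 2 and 8 of 13 for mitochondrially encoded genes and 10 and 12 of 24 for the ATF4 response. They numbered 14 and 6 of 23 for TNF and NF-kB targets and 7 and 9 of 25 for interferon response (7 and 8 when adjusted over the list alone). They numbered 9 and 10 of 22 for mesenchymal, 4 and 1 of 10 for epithelial (3 and 1 over the list alone), 0 and 3 of 4 for squamous and 3 and 0 of 6 for alveolar and club cell markers. They numbered 23 and 23 of 51 for G2 and M phase, 8 and 5 of 19 for p53 targets, and 14 and 11 of 31 for glycolysis and hypoxia. Among markers of other cell types they numbered 0 and 1 of 4 for leukocyte (0 over the list alone), 6 and 2 of 9 for fibroblast (7 and 2 over the list alone) and 1 and 2 of 4 for endothelial markers. Within the mitochondrially encoded list, mt-Cytb fell from 3515 ± 52.2 to 1368 ± 11.7 CPM while mt-Co1 rose from 9199 ± 110 to 17700 ± 168 CPM, so its members moved apart. The ATF4 list had a median of -0.083 and a mean of 0.15, the mesenchymal list -0.038 and 0.13, and the interferon list 0.12 and -0.043; camera placed the first 2 of these lower and the third higher. The leukocyte list had a median of 0.035 with a lower placing.

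**Figure D1:**
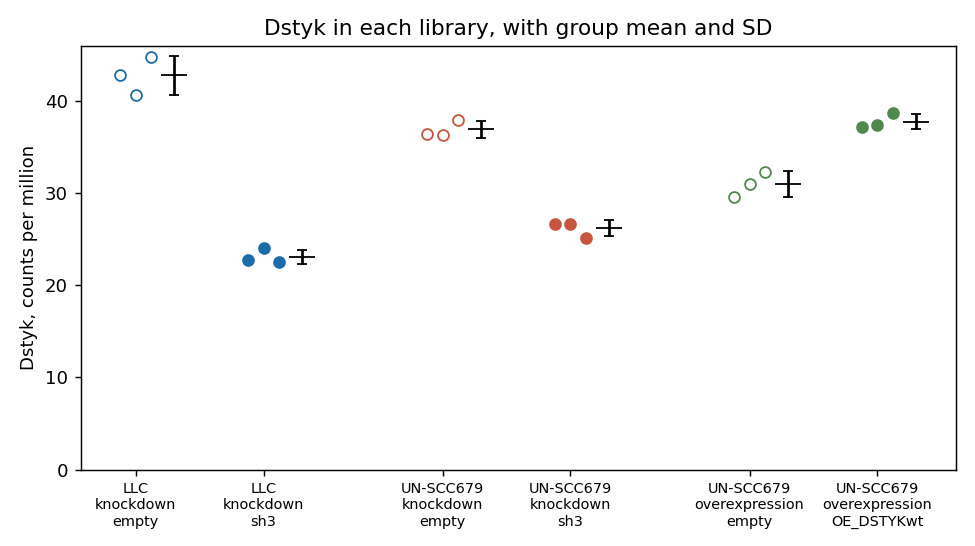
Dstyk in CPM (vertical axis, from 0) in each of the 18 libraries, with open points for empty-vector libraries, filled points for sh3 or OE_DSTYKwt libraries, and a bar for the mean ± SD of each group of 3. Group means are 42.75 and 23.07 CPM in LLC, 36.89 and 26.15 CPM in the UN-SCC679 knockdown, and 30.97 and 37.75 CPM in the UN-SCC679 overexpression, and no library of one arm overlaps the other arm of its experiment.

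In UN-SCC679, Dstyk fell from 36.89 ± 0.931 to 26.15 ± 0.870 CPM with sh3 (SD, n = 3), a 1.41-fold reduction (log2 -0.50, SE 0.040; adjusted p = 5.61e-07, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), again without overlap between the arms. Of 14271 tested genes, 9112 (63.8%) passed the test, 4541 higher and 4571 lower (5333 and 3753 when scaled by library size alone). At least 2-fold changes numbered 1471, of which 1147 were rises and 324 falls, against 602 in all with limma on log2(TPM + 1). The groups did not overlap for 68.2% of genes, where chance gives 10%. The TPLKO and pLENTI6 empty-vector populations of UN-SCC679, which also differ in vector and doxycycline, differed for 9675 of 14080 genes (68.7%). Of these, 2030 differed at least 2-fold. Counts of this size therefore do not by themselves mark a response to DSTYK.

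Several genes in UN-SCC679 were near silent in the empty TPLKO libraries and clearly expressed in the sh3 libraries. Trim30d, of a family with near-identical members, had 0 counts in the 3 empty libraries and 2858 in the 3 sh3 libraries (22.2 ± 0.327 CPM), and the imprinted gene Peg10 had 2 and 3737 counts. Complement C3 rose from 9 to 3102 counts (24.1 ± 1.75 CPM with sh3). Lox, which cross-links collagen and elastin, rose from 0.220 ± 0.132 to 30.6 ± 1.69 CPM (137-fold). The ferritin receptor gene Scara5 rose from 0.474 ± 0.0296 to 64.9 ± 1.65 CPM (136-fold), and Nqo1 from 0.508 ± 0.139 to 37.3 ± 1.17 CPM (72.2-fold). Among genes with a mean log2 CPM of at least 3 and no overlap between the arms, the largest falls were those of Samd12 (8.51-fold) and Klhl30 (7.36-fold). Lama5, the laminin alpha-5 chain, fell from 98.7 ± 1.60 to 17.8 ± 1.14 CPM (5.55-fold), and Gpnmb, a transmembrane glycoprotein of lysosome-related organelles, from 40.6 ± 0.10 to 7.53 ± 0.138 CPM (5.39-fold). The adjusted p of these genes was at most 5.69e-10 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 per group).

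Genes of the unfolded protein response fell in UN-SCC679, 18 of 19 against 1 that rose (median -0.49). Hspa5, the main chaperone of the endoplasmic reticulum, fell from 3290 ± 36.8 to 1680 ± 11.3 CPM (1.96-fold) and the calcium-binding chaperone gene Calr from 3182 ± 6.87 to 2031 ± 6.37 CPM (1.57-fold). The NRF2 list rose in 20 of 21 cases and fell in 1 (median 0.58), with the glutathione transferase genes Gstm1 up 4.48-fold and Gsta4 up 3.70-fold. TNF and NF-kB targets rose in 18 of 24 cases and fell in 1 (19 and 2 when adjusted over the list alone; median 0.47), with the chemokine genes Cxcl5 up 4.81-fold and Cxcl1 up 2.88-fold. Lysosome genes fell in 21 of 35 cases and rose in 8 (median -0.27); Lamp1, an abundant lysosomal membrane protein, fell from 1299 ± 18.5 to 785 ± 7.79 CPM. The ATF4 amino acid response fell in 16 of 24 cases and rose in 6 (median -0.47, mean -0.039), with the amino acid transporter gene Slc7a5 down 1.70-fold. Mitochondrially encoded genes rose in 12 of 13 cases and fell in 0 (median 0.37), with mt-Nd4 up 1.31-fold. Camera's adjusted p (Benjamini-Hochberg) was 1.80e-09 for the unfolded protein response, 7.81e-10 for NRF2, 3.55e-04 for TNF and NF-kB, 0.00266 for lysosome, 0.00409 for ATF4 and 8.37e-06 for mitochondrially encoded genes. With an estimated correlation these were adjusted p = 0.0849, 0.0798, 0.170, 0.337, 0.214 and 0.179.

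Cell-cycle and biosynthesis lists also moved in UN-SCC679. S phase genes fell in 32 of 42 cases and rose in 2 (33 and 2 when adjusted over the list alone; median -0.23), with Rrm2, a subunit of ribonucleotide reductase, down 1.47-fold and Mcm2 down 1.45-fold. G2 and M phase genes fell in 27 of 51 cases and rose in 9 (median -0.082), with Top2a down 1.31-fold and Psrc1 up 2.94-fold. Cholesterol synthesis genes fell in 17 of 23 cases and rose in 3 (median -0.24), with the sterol oxidase gene Msmo1 down 1.94-fold and Fdps, which makes farnesyl diphosphate, down 1.55-fold. Ribosomal protein genes rose in 56 of 74 cases and fell in 2 (median 0.14). Fibroblast markers rose in 5 of 7 cases and fell in 0 (median 0.89), led by Pdgfra, from 6.86 ± 0.417 to 56.3 ± 1.65 CPM (8.21-fold). Camera's adjusted p (Benjamini-Hochberg) was 7.37e-06 for S phase, 0.0191 for G2 and M phase, 2.05e-04 for cholesterol synthesis, 2.96e-07 for ribosomal proteins and 0.0331 for fibroblast markers. With an estimated correlation the adjusted p was 0.170, 0.236, 0.214, 0.236 and 0.236. The G2 and M phase call was lost with the filter of 1 CPM (adjusted p = 0.0542) and with camera.DGEList (adjusted p = 0.153); over all alternatives its adjusted p ran from 0.00751 to 0.236.

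In all, 11 lists were called in the UN-SCC679 knockdown, and other splits of its libraries called up to 9. The remaining lists were not called there (camera's adjusted p from 0.0542 to 0.993), although single members changed strongly. With camera.DGEList the mesenchymal (adjusted p = 1.11e-08, alternatives to 0.336), ERK target (0.00655, alternatives to 0.336) and killing lists (0.0281, alternatives from 0.0225 to 0.236) were called higher. The squamous and killing lists were called without some single libraries and with the per-chromosome offset (adjusted p = 0.0358 and 0.0225), and the mesenchymal list without empty TPLKO replicate 1 (0.0478); the squamous alternatives ran to 0.336. Of 24 mesenchymal markers 13 rose and 6 fell, and the matrix genes Postn and Fn1 rose from 30.7 ± 0.720 to 322 ± 3.02 CPM (10.5-fold) and from 384 ± 12.1 to 1741 ± 34.6 CPM (4.54-fold). Of 12 squamous markers 8 rose and 2 fell (9 and 2 over the list alone). Trp63, the transcription factor of basal and squamous epithelium, went from 2.19 ± 0.212 to 13.5 ± 0.351 CPM and Krt14 from 3.07 ± 0.294 to 14.1 ± 0.519 CPM. Of 21 ERK pathway targets 12 rose and 5 fell, with the immediate-early gene Egr1 up 9.12-fold. Of 20 p53 targets 11 rose and 7 fell, with the death receptor gene Fas up 11.4-fold and Pmaip1, a BH3-only activator of cell death, down 3.81-fold. Of 19 killing ligands and receptors 12 rose and 4 fell, with Lgals9 up 2.04-fold and the granzyme inhibitor gene Serpinb9 down 1.61-fold.

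Of 16 MHC class I genes 8 rose and 5 fell (median 0.12); the H2 genes lie on chromosome 17, whose 733 tested genes had a median log2 change of 0.25 in this comparison, and with each chromosome's median removed the list's median was -0.11. Chromosome medians of 0.29 on chromosome 19, 0.16 on chromosome 16 and -0.19 on chromosome 8 stood outside the range of random gene sets of the same size, which reached at most 0.088 and at least -0.067. Interferon response genes rose in 13 and fell in 12 of 35 cases. Other counts of higher and lower members were 9 and 13 of 31 for autophagy, 21 and 34 of 72 for nuclear genes of oxidative phosphorylation (22 and 35 over the list alone) and 12 and 10 of 31 for glycolysis and hypoxia. Among markers they were 3 and 2 of 8 for epithelial markers, 3 and 2 of 6 for alveolar and club cell markers (3 and 3 over the list alone), 4 and 0 of 5 for leukocyte markers and 2 and 0 of 4 for endothelial markers (1 and 0 over the list alone). The epithelial list had a median of -0.14 and a mean of 0.97, and camera placed it lower; its keratin genes Krt8 and Krt18 fell 1.54-fold and 1.74-fold.

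**Figure D2:**
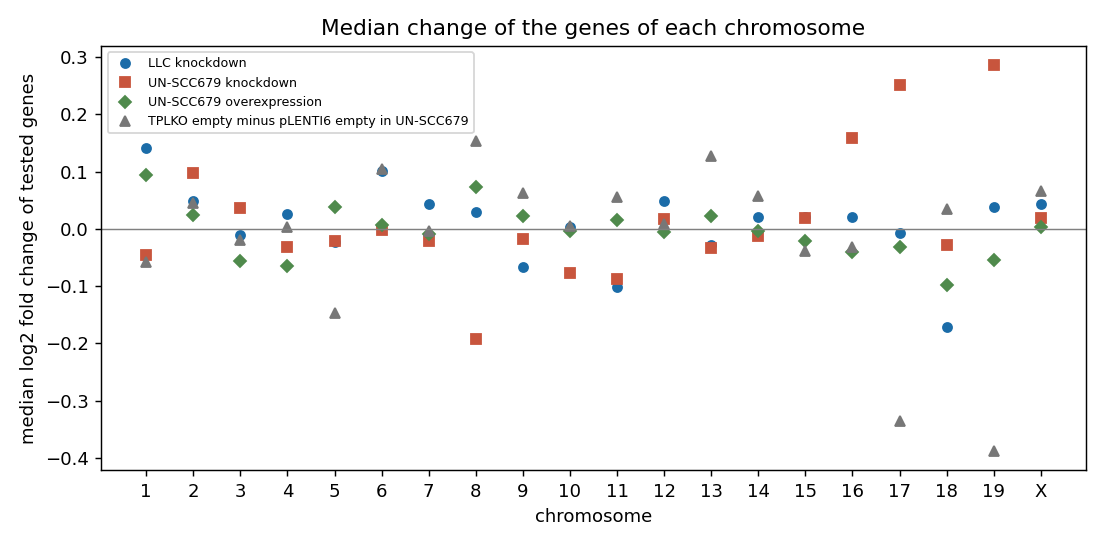
Median log2 fold change (vertical axis) of the tested genes of each chromosome (horizontal axis) in the 3 comparisons, and between both empty-vector populations of UN-SCC679 (TPLKO minus pLENTI6). The UN-SCC679 knockdown reaches 0.29 on chromosome 19 and 0.25 on chromosome 17, where the difference between the empty-vector populations is -0.39 and -0.34.

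With the DSTYK construct in UN-SCC679, Dstyk rose from 30.97 ± 1.39 to 37.75 ± 0.774 CPM (SD, n = 3), a 1.22-fold increase (log2 0.28, SE 0.040; adjusted p = 6.41e-04, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The arms did not overlap, and the median log2 change of the genes of chromosome 1, where Dstyk lies, was 0.094. Counts were assigned to mouse transcripts, and the sequence of the construct was not analysed here, so construct-derived reads that differ from the mouse reference are outside this value. Of 13975 tested genes, 4153 (29.7%) passed the test, 2034 higher and 2119 lower (1778 and 1242 with limma on log2(TPM + 1)). At least 2-fold changes were 114 rises and 241 falls, 355 in all, against 208 with the filter of 1 CPM and 76 with limma on log2(TPM + 1). The groups did not overlap for 46% of genes, where chance gives 10%.

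Among genes with a mean log2 CPM of at least 3 and no overlap between the arms, the largest changes of the overexpression were falls. Crabp1, a retinoic acid binding protein, fell from 30.9 ± 2.90 to 0.108 ± 0.0634 CPM (14 counts in the OE_DSTYKwt libraries), and Ly6a, also called Sca-1 and of a family with similar members, from 24.1 ± 1.76 to 0.0868 ± 0.0379 CPM (11 counts). Akap12, a scaffold of protein kinase A, fell 14-fold, the matrix gene Tnc fell 9.95-fold, and Marcks, a substrate of protein kinase C, fell from 27.9 ± 0.995 to 3.39 ± 0.167 CPM (8.23-fold). Rises were smaller. Gas1 rose 2.51-fold, the ligand gene Wnt5a 2.42-fold, the aminopeptidase gene Anpep 2.39-fold and Pdgfra 2.03-fold. These genes had an adjusted p of at most 2.99e-05 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

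Glycolysis and hypoxia genes fell with the DSTYK construct in 17 of 30 cases and rose in 3 (19 and 4 when adjusted over the list alone; median -0.16), with the glucose transporter gene Slc2a1 down 1.51-fold and Pfkfb3 up 1.62-fold. Genes of the unfolded protein response fell in 12 of 19 cases and rose in 1 (13 and 1 over the list alone; median -0.099), with Sdf2l1 down 1.48-fold. Cholesterol synthesis genes fell in 12 of 23 cases and rose in 0 (median -0.11), with Fdps down 1.20-fold. Interferon response genes rose in 14 of 35 cases and fell in 5 (14 and 6 over the list alone), with a median of 0.14 and a mean of -0.028. Rsad2, an antiviral enzyme, fell from 1.71 ± 0.204 to 0.0709 ± 0.0423 CPM and the RNA sensor gene Dhx58 rose 1.54-fold. Squamous markers rose in 6 of 9 cases and fell in 2 (median 0.29), with Trp63 up 2.19-fold and the desmosome gene Pkp1 up 1.28-fold, and 2 of 3 fibroblast markers rose and 0 fell (median 0.22). Camera's adjusted p (Benjamini-Hochberg) was 6.42e-05 for glycolysis and hypoxia, 2.31e-05 for the unfolded protein response, 0.00197 for cholesterol synthesis, 0.0191 for interferon response, 0.0383 for squamous and 0.0353 for fibroblast markers. With an estimated correlation the adjusted p was 0.236, 0.236, 0.188, 0.214, 0.236 and 0.337. The interferon call was lost with camera.DGEList (adjusted p = 0.0700, alternatives from 0.00645 to 0.214). The squamous call was lost with the filter of 1 CPM (adjusted p = 0.0805), with the replicate block (0.0526) and without pLENTI6 empty replicate 2 or 3 (0.0527 and 0.0502; alternatives from 0.0163 to 0.236). The fibroblast call was lost without OE_DSTYKwt replicate 1 (adjusted p = 0.0509, alternatives from 0.0117 to 0.337).

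Ribosomal protein genes fell with the DSTYK construct in 15 of 74 cases and rose in 2 (9 and 2 when adjusted over the list alone; median -0.085). Nuclear genes of oxidative phosphorylation fell in 11 of 72 cases and rose in 5 (10 and 3 over the list alone; median -0.057). Camera's adjusted p (Benjamini-Hochberg) was 4.86e-04 and 0.0153, and with an estimated correlation the adjusted p was 0.751 and 0.758. The first pLENTI6 empty library stood apart from the rest of its group, with 5.66% of its counts in ribosomal protein genes against 5.16% and 5.02%, and without it both calls were lost (adjusted p = 0.155 and 0.469, medians -0.031 and -0.011). The oxidative phosphorylation call was also lost without OE_DSTYKwt replicate 1 (0.0530) and with camera.DGEList (0.101); over all alternatives the adjusted p ran from 1.70e-08 to 0.751 for ribosomal proteins and from 8.59e-05 to 0.758 for oxidative phosphorylation. Without that empty library 4939 genes were called in all, of which 390 changed at least 2-fold.

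In all, 8 lists were called in the overexpression, and other splits of its libraries called up to 6. The other lists were not called (camera's adjusted p from 0.0508 to 0.994). The epithelial list was called lower under 7 alternatives, among them camera.DGEList (adjusted p = 0.00391), the filter of 1 CPM (0.0179) and the replicate block (0.0376), over alternatives from 0.00391 to 0.336. The mesenchymal list was called lower with camera.DGEList (0.0447, alternatives to 0.758), and the mitochondrially encoded list without pLENTI6 empty replicate 1 (0.00355, alternatives to 0.753). Higher and lower members numbered 10 and 4 of 35 for lysosome, where Gpnmb fell 1.86-fold, 6 and 3 of 31 for autophagy (8 and 4 over the list alone), 0 and 2 of 13 for mitochondrially encoded genes (0 and 0 over the list alone). They numbered 7 and 2 of 22 for the ATF4 response (7 and 3) and 4 and 6 of 21 for NRF2 (5 and 7), where Nqo1 fell 2.09-fold. They numbered 5 and 9 of 23 for TNF and NF-kB targets, 1 and 3 of 16 for MHC class I, 4 and 4 of 18 for killing ligands and receptors and 4 and 5 of 42 for S phase. Other numbers were 5 and 9 of 51 for G2 and M phase, 3 and 5 of 20 for p53 targets (4 and 5) and 5 and 8 of 21 for ERK targets, where the feedback inhibitor gene Spry1 fell 2.81-fold. Among markers they numbered 0 and 4 of 8 for epithelial, 5 and 7 of 21 for mesenchymal, 2 and 0 of 5 for alveolar and club cell, 0 and 0 of 4 for leukocyte and 0 and 0 of 3 for endothelial genes. Median, mean and placing by camera differed in sign for the mesenchymal (0.003, -0.12, lower), leukocyte (-0.070, -0.077, higher) and endothelial lists (0.052, 0.13, lower).

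**Figure D3:**
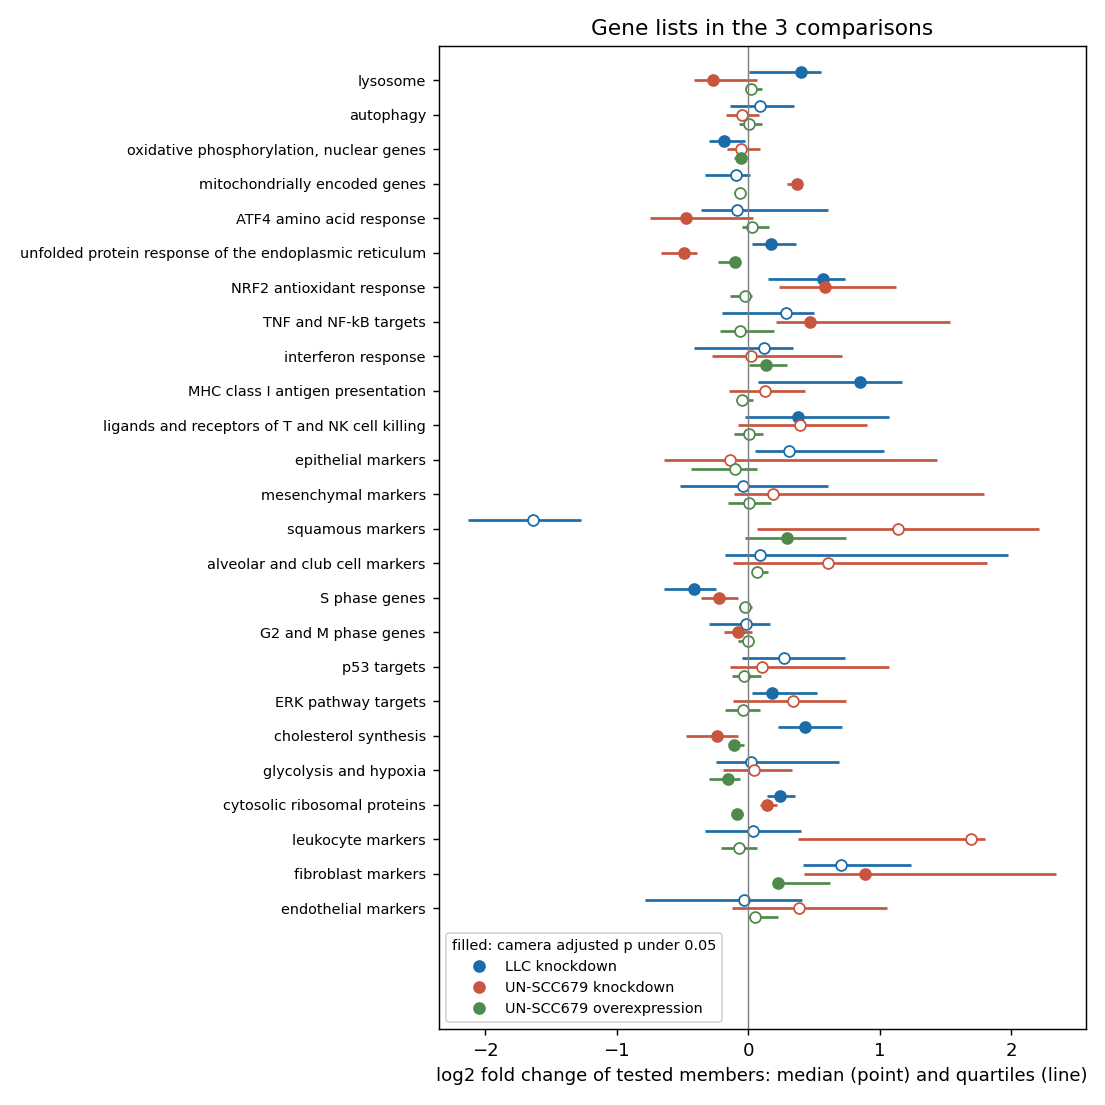
Log2 fold change (horizontal axis) of the tested members of the 25 gene lists in the 3 comparisons, as the median (point) and quartiles (line), with filled points where camera's adjusted p was under 0.05. The unfolded protein response has medians of 0.17 in LLC and -0.49 in the UN-SCC679 knockdown, and the NRF2 list of 0.57 and 0.58.

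The test of the difference between the knockdown effects of the 2 lines called 9233 of 15399 genes (60%), of which 2393 differed at least 2-fold. The unfolded protein response and cholesterol synthesis rose in LLC and fell in UN-SCC679, with median differences (UN-SCC679 minus LLC, log2) of -0.78 and -0.67. Camera's adjusted p (Benjamini-Hochberg over the 25 lists) was 2.11e-10 and 2.59e-09, and both calls held with an estimated correlation (adjusted p = 0.00751 and 0.00727). Within the single lines the calls of both lists did not hold in that way (adjusted p = 0.246 and 0.119 in LLC, 0.0849 and 0.214 in UN-SCC679). Lysosome genes differed by -0.48 (adjusted p = 6.34e-09, or 0.0698 with an estimated correlation), MHC class I genes by -0.57 (0.00486, or 0.0637 with an estimated correlation) and mitochondrially encoded genes by 0.46 (1.13e-04, or 0.128 with an estimated correlation). S phase, oxidative phosphorylation and ribosomal protein genes differed by 0.18, 0.13 and -0.083 (adjusted p = 0.00849, 0.0302 and 0.0391, and with an estimated correlation 0.128, 0.366 and 0.584). For NRF2 genes the median difference was 0.43 and did not pass the test (adjusted p = 0.239).

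Both knockdowns moved 4148 of the 12834 genes tested in both lines in the same direction, against 3116 expected of independent lists, with 1948 higher in both and 2200 lower in both. Opposite directions were taken by 2666 genes, against 3111 expected. At least 2-fold, 229 genes changed in the same direction (58.9 expected) and 84 in opposite directions (42.6 expected), and with the filter of 1 CPM the first number was 146. Spearman's correlation of log2 fold changes across genes, which are not independent replicates, was 0.16. Between the LLC knockdown and the UN-SCC679 overexpression it was 0.026, yet 30 genes changed at least 2-fold in the same direction (9 expected) and 34 in opposite directions (11 expected). An excess over independent lists alone therefore does not mark a shared response. Rises shared by both knockdowns included Pdcd4, a translation inhibitor, 3.60-fold in LLC and 3.85-fold in UN-SCC679, the complement protease gene C1ra, 3.72-fold and 3.54-fold, and Nqo1, 3.49-fold and 72.2-fold. Shared falls included the secreted guidance cue gene Sema3c, 2.42-fold and 3.88-fold, Armc6, 2.15-fold and 2.51-fold, and Col7a1, the collagen of anchoring fibrils, 3.64-fold and 2.13-fold.

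In UN-SCC679, knockdown and overexpression moved 1931 of 13430 genes in the same direction, against 1336 expected of independent lists, and 1243 in opposite directions, against 1334 expected. At least 2-fold, 138 genes went in the same direction (11.1 expected) and 61 in opposite directions (15.2 expected), of which 59 rose in the knockdown and fell in the overexpression. Genes under a mean log2 CPM of 3 in either comparison held 59 of the 61, against 36.3 expected among them (ratio 1.62). Of the 61, 46 (75.4%) also differed at least 2-fold between the empty-vector populations. The share was 47.6% for genes changed at least 2-fold in 1 of the comparisons and 7.9% for genes changed that much in neither. Those populations are the controls of both comparisons, which by itself raises the share for opposite directions. Without OE_DSTYKwt replicate 2 the number in opposite directions was 823, and with the filter of 1 CPM the 61 became 36. Spearman's correlation across genes was 0.16. Marcks rose 2.61-fold in the knockdown and fell 8.23-fold in the overexpression, Tmem176b rose 2.66-fold and fell 6.44-fold, and Ly6e rose 27.4-fold and fell 1.60-fold. Adgra2, a receptor of the adhesion class, fell 1.5-fold in the knockdown and rose 1.82-fold in the overexpression, and the secreted glycoprotein gene Stc2 fell 1.49-fold and rose 1.49-fold.

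The difference between knockdown and overexpression effects in UN-SCC679 was called for 7777 of 14975 genes (51.9%), of which 1349 differed at least 2-fold. NRF2 genes had a median difference (knockdown minus overexpression, log2) of 0.75 and the unfolded protein response of -0.39. The unfolded protein response was lower in both, with medians of -0.49 in the knockdown and -0.099 in the overexpression, so its difference is one of size. For the NRF2 and unfolded protein response differences, camera's adjusted p (Benjamini-Hochberg over the 25 lists) was 4.59e-11 and 3.59e-08. Both calls held with an estimated correlation (adjusted p = 0.00453 and 0.0373). These lists and the unfolded protein response and cholesterol synthesis between the lines were the calls among all list tests that held in that way. The single comparisons had fewer libraries and were adjusted over more tests, so this does not set the differences above the single effects. Ribosomal protein genes differed by 0.23 (adjusted p = 3.02e-07, or 0.450 with an estimated correlation), S phase genes by -0.18 (5.22e-05, or 0.0576 with an estimated correlation). TNF and NF-kB targets differed by 0.57 (3.43e-04, or 0.0730 with an estimated correlation) and the ATF4 response by -0.44 (2.96e-04, or 0.106 with an estimated correlation). Also called were the lysosome, mitochondrially encoded, mesenchymal, ERK target, cholesterol synthesis, killing and glycolysis lists (camera's adjusted p from 2.96e-04 to 0.0111). With an estimated correlation their adjusted p ran from 0.0783 to 0.222.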

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

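The tests of differences between effects and the regroupings of libraries in this part were planned before their results were seen. The knockdown effects of LLC and UN-SCC679 differed for 9233 genes by the interaction test. Median differences (UN-SCC679 minus LLC, log2) were -0.483 for lysosome genes, -0.779 for the unfolded protein response and -0.668 for cholesterol synthesis; each of these lists was called higher in LLC and lower in UN-SCC679 with the preset correlation. The adjusted p of camera with an estimated correlation was 0.170, 0.246 and 0.119 in LLC and 0.337, 0.0849 and 0.214 in UN-SCC679, and for the differences 0.0698, 0.00751 and 0.00727. In 100 regroupings of the libraries within each line, 1, the real one, gave as many genes, and the highest of the others gave 5070. Other splits of a single line called 1 gene at most, so the other draws held the effect of 1 line at most. The regroupings therefore do not decide whether the effects of the lines differ. Draws that kept neither real grouping gave 0 genes at most. The lines also differ in strain and tumour type, and 1 hairpin was used, so what in the lines goes with the difference was not tested.

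In UN-SCC679, knockdown and overexpression effects differed for 7777 genes, and 1 of 100 regroupings, the real one, gave as many, with 6411 as the highest of the others and 3 as the highest without either real grouping. As between the lines, the regroupings do not decide whether these effects differ. Ribosomal protein genes were called higher in the knockdown and lower in the overexpression, with a median difference of 0.228. The list's adjusted p in camera with an estimated correlation was 0.236 in the knockdown, 0.751 in the overexpression and 0.450 for the difference, and without pLENTI6 empty replicate 1 the call in the overexpression was lost (adjusted p = 0.155, median -0.031; alternatives from 1.70e-08 to 0.751). For the 4148 genes changed in the same direction in both knockdowns, 1 of 100 regroupings reached the real number and the highest other gave 0. For the 1243 genes changed in opposite directions by knockdown and overexpression, 2 of 100 did: the real one and the one with the arms of one experiment exchanged, which turns the 1931 genes of the same direction into opposite ones. Other splits of a single comparison called 1 gene at most, so these overlaps could not come out otherwise, and the regroupings say nothing about whether the calls coincide. The 1243 opposite calls are fewer than the 1334 expected of independent lists.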

How the results depend on the processing

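The tests with a per-chromosome offset and with camera.DGEList were chosen after the result was seen, as was the 2-fold count under each setting. Of 226 results for named genes, 214 kept their call in all settings that tested them, 12 lost it in some and 0 reversed. Some of these genes were not tested with the filter of 1 CPM or with protein-coding genes alone. Named genes were picked for large or strongly called changes in these same libraries, so few losses were to be seen by construction. Of 29 called lists, 23 kept their call in every setting except the estimated correlation and 6 lost it in some. With an estimated correlation 0 lists were called in each comparison. That setting also rests on 4 residual degrees of freedom, so the lost calls do not measure correlation between members alone. In LLC the NRF2 list had an estimated correlation of -0.042, below the preset 0.01, yet its unadjusted camera p rose from 7.1e-06 to 0.0079. A size limit of 2-fold left 1683, 1471 and 355 changed genes in the LLC knockdown, UN-SCC679 knockdown and overexpression, by construction. Limma on log2(TPM + 1) gave 666, 602 and 76 genes changed at least 2-fold; the added 1 lowers the fold of low genes by construction. The filter of 1 CPM gave 208 in the overexpression, 146 shared by the knockdowns and 36 opposite between knockdown and overexpression, with fewer genes tested. Removing each chromosome's median gave 9949, 8851 and 3629 changed genes and log2 changes of Dstyk of -1.03, -0.45 and 0.19.

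Leaving out each library in turn gave 9650 to 9846 changed genes in LLC (2-fold 1683 to 1758, Dstyk -0.93 to -0.86, lists 10 to 11), 8530 to 8828 in the UN-SCC679 knockdown (1498 to 1554, -0.51 to -0.47, 11 to 14) and 2876 to 4939 in the overexpression (352 to 390, 0.25 to 0.32, 6 to 9). Differences ranged from 8974 to 9045 genes between lines and from 7277 to 7892 between knockdown and overexpression, shared calls from 3886 to 4096 (2-fold 228 to 242) and opposite calls from 823, without OE_DSTYKwt replicate 2, to 1555 (2-fold 56 to 67). The cause was not tested.

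In 26 cases a list's test reversed under a setting, of which 0 were called there; the cause was not tested. With camera.DGEList the medians were 0.035 (LLC leukocyte), 0.017 (UN-SCC679 knockdown interferon) and 0.052 (overexpression endothelial). With the per-chromosome offset they were 0.171 (LLC leukocyte) and, in the UN-SCC679 knockdown, 0.606 (alveolar and club cell markers list in UN-SCC679 knockdown), -0.015 (autophagy) and -0.107 (MHC class I), and in the overexpression 0.007 (autophagy) and 0.001 (killing ligands). With the filter of 1 CPM they were 0.014 (interferon) and -0.076 (alveolar) in the UN-SCC679 knockdown; some lists kept under 3 members there and have no value. Leaving out libraries gave medians from -0.066 to 0.121 (LLC leukocyte), from -0.516 to 0.373 (UN-SCC679 knockdown epithelial), from -0.013 to 0.032 (its interferon list), and in the overexpression from -0.066 to 0.351 (endothelial), from -0.114 to -0.014 (leukocyte) and from -0.022 to 0.033 (killing ligands).

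The labels do not say whether replicate numbers pair the libraries. Same-number correlations of deviations ran from -0.084 to 0.095, and each sample correlated best with its own number in the UN-SCC679 knockdown alone. With so few libraries per arm this does not settle whether they are paired. With a replicate block 9925, 8806 and 3771 genes changed (Dstyk -0.89, -0.50 and 0.29, lists 10, 11 and 8), the differences were 9058 and 7421, shared calls 4014 and opposite calls 1084; the squamous call of the overexpression was lost (adjusted p = 0.0526, camera) and the endothelial median there was 0.048.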

Other observations

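The tests of windows along chromosomes, of chromosomes 1 and 18, and of swapped libraries were chosen after the result was seen; the others here were planned. Lineage markers separated the lines in CPM scaled over all 18 libraries (mean ± SD, n = 3). Sox2, a transcription factor of squamous lung cancer, was 0 CPM in LLC, 35.3 ± 3.69 in UN-SCC679 with empty TPLKO and 80.7 ± 4.10 with empty pLENTI6. Nkx2-1, a lung lineage factor of alveolar cells, was 56.0 ± 1.35 and 36.5 ± 0.191 in those UN-SCC679 groups and 0 in LLC with empty TPLKO. Krt8, a keratin of simple epithelium, was 437 ± 11.2 and 574 ± 20.3 CPM in UN-SCC679 and 0.600 ± 0.138 in LLC, while the basal keratin gene Krt5 was at most 0.0389 and the epithelial cadherin gene Cdh1 at most 0.328 CPM in any group. The empty-vector populations of UN-SCC679, which also differ in vector and doxycycline, differed for 9675 of 14080 genes (68.7%, edgeR quasi-likelihood test), 2030 of them at least 2-fold.

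Whole chromosomes shifted in the UN-SCC679 knockdown, with medians of 0.29 on chromosome 19, 0.25 on chromosome 17, 0.16 on chromosome 16 and -0.19 on chromosome 8; smaller shifts outside the range of random gene sets included chromosomes 1 and 18 in LLC (0.14 and -0.17) and in the overexpression (0.094 and -0.098) and chromosome 1 in this knockdown (-0.045), and their causes were not tested. After correction for GC content and length, which moved 3505 genes by more than 0.05, chromosome 19 stayed at 0.281 (95% bootstrap interval 0.236 to 0.325), which argues against that bias as the whole cause. Of the 10 Mb windows on these chromosomes, 100% had their chromosome's sign, which argues against a few regions. Copy number differing between populations of the line is a candidate explanation: between the empty populations (TPLKO minus pLENTI6) chromosome 19 differed by -0.388, chromosome 17 by -0.34 and chromosome 8 by 0.15, each opposite in sign to its shift in the knockdown, but chromosome 16 by -0.031, and the knockdown shares the TPLKO libraries with that contrast. On chromosomes 19 and 17 the empty TPLKO population thus lay below both the sh3 and the empty pLENTI6 population, and on chromosome 8 above both. The shifts of these chromosomes may therefore lie in the control arm. In the overexpression, which shares no library with the knockdown, chromosomes 19, 17, 16 and 8 had medians of -0.055, -0.031, -0.041 and 0.074. Each was outside the range of random sets and opposite in sign to the knockdown, but chromosomes 3 and 4 also had medians of -0.056 and -0.065 there. In the LLC knockdown, where Dstyk fell more, chromosomes 19, 17, 16 and 8 had medians of 0.038, -0.008, 0.021 and 0.03, inside the range of random sets. An effect of DSTYK in UN-SCC679 stays open beside copy number, which was not analysed in DNA here.

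Dstyk rose 1.22-fold with the DSTYK construct, a small rise for an overexpression. Less the median of chromosome 1 the log2 change was 0.191, above 2 SE of 0.080. In the fit with the per-chromosome offset, added after the data were seen, the rise was still called (adjusted p = 0.00688, edgeR quasi-likelihood test). The chromosome's median thus does not account for the whole rise. But 15% of the genes of chromosome 1 rose more than Dstyk, so a shift of the chromosome stays open. The lowest OE_DSTYKwt library lay 4.88 CPM above the highest empty library, which argues against an exchange of libraries between the arms. Reads of a construct whose sequence differs from the mouse reference may be missing from the 0.191; the construct was not analysed here, so this stays open too.

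Knockdown and overexpression in UN-SCC679 moved 138 genes at least 2-fold in the same direction, against 11.1 expected of independent lists. Among genes at a mean log2 CPM of at least 3 the number was 9 against 0.30 expected (ratio 30.18), which argues against low counts for those genes, while the remaining 129 against 25.6 expected (ratio 5.04) have low counts. Genes that drift between populations of the line could add to both comparisons: 42.5% of the 127 same-direction genes that were also tested there differed at least 2-fold between the empty populations, against 47.6% of genes changed at least 2-fold in 1 comparison, 75.4% of the 61 opposite-direction genes and 7.9% of genes changed that much in neither. The first against the second is a ratio of 0.89 (95% bootstrap interval 0.71 to 1.09, added after the ratio was seen; the planned reading, that a ratio no higher than 1 argues against drift, left the shared controls out of account). The empty libraries are also the controls of both comparisons, which by itself lowers the share for same-direction genes and raises it for opposite ones, so the ratio decides nothing and the explanation stays open, as does a response to either change of DSTYK, which was not tested.

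With 3 libraries against 3 there are 10 splits, which cannot give a share under 0.05, and in each comparison 1 of 10, the real one, reached the real numbers. In LLC these were 9995 changed genes, 1683 at least 2-fold and 10 lists, and the highest other split gave 0, 0 and 8. In the UN-SCC679 knockdown they were 9112, 1471 and 11, with 1, 1 and 9 as the highest others, and in the overexpression 4153, 355 and 8, with 1, 1 and 6.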
